A study of Mus musculus with 12 samples.

How the data were processed

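Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 2 mouse melanoma cell lines, per the labels: line 971, which is wild type (WT) for Kmt2d, and line 493, which carries a Kmt2d mutation. Kmt2d encodes a histone methyltransferase that places H3K4me1 at enhancers. Each line was profiled for 4 histone marks: H3K4me1 and H3K27ac (found at active enhancers), H3K4me3 (active promoters) and H3K27me3 (Polycomb repression). There was 1 library per line and mark, so 8 ChIP libraries, together with 4 input libraries whose reads are not analysed here. The cells were grown in DMEM/F12 with serum and the antibodies came from Abcam, per the labels. Nothing in the labels says how the mutation was made or which tumours the lines came from.

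The values start from the peak lists that the authors deposited, 1 list per library, with no pooling of libraries. The genome build was mm10, and FastQC, MultiQC and MACS2 were used, per the submitters' processing notes, which give no versions. The read aligner, read filters and sequencing depth are not given in the sources used here. In the MACS2 lists each peak has a fold enrichment over its control (a ratio) and −log10 p and −log10 q values, all as deposited by the authors. The deposited score column of these lists is a rescaled −log10 value and was not used. The H3K4me3 lists are in the older MACS layout, and their deposited score is −10 times the log10 of the peak's p value, with a smallest value of 50. The position of the H3K27ac summit, deposited as an offset in bases, was not used.

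The deposited lists differ in threshold and control, as their file names and values show. The H3K27ac lists were called against each line's own input, with a smallest −log10 q of 1.30. The H3K4me1 lists and the WT H3K27me3 list were also called against own input, with a smallest −log10 p of 5.01 in both WT lists. The name of the mutant H3K27me3 list gives the WT H3K27me3 library as its control, and its smallest −log10 q was 1.01. It would therefore hold regions higher in the mutant than in the WT line, and its peak number was not compared with that of the WT list. All statements on regions with more H3K27me3 in the mutant line rest on that name. Scores, folds and p values are those of the authors and served to describe and rank peaks within a list. For H3K27ac, fold and p also gave inferred summit fragments and background, which were compared between the lines.

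Peaks on the 19 autosomes and on X and Y were kept, and those on other contigs were left out. A peak counted as shared when at least 1 bp overlapped a peak of the other list. Because H3K27ac peaks were narrow (median widths of 116 bp and 107 bp), shares were also computed within 1 kb. Overlaps of lists with themselves placed at random on the same chromosome (100 placements) are given as background. Gene models came from a RefSeq gene table of GRCm38, the assembly of mm10. That table holds gene starts and ends without strand, so a promoter peak was one within 1 kb of either end of a gene model, in place of the transcription start that the plan named. Peak classes used 34614 protein-coding and lncRNA genes, and gene counts used 21887 protein-coding genes. All other peaks are called distal. Coordinates are 1-based positions on mm10.

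For each gene, the bases covered by peaks within 50 kb of either gene end were summed in each line. The mean difference, mutant minus WT, of 16 gene lists was placed among 10000 random lists of the same size drawn from the same of 10 equal groups of genes by mean coverage. A list below the 2.5 or above the 97.5 percentile is called outside the range of random lists. These percentiles describe these libraries and are not p values. With 16 lists per mark, 0.8 would lie outside by chance. The lists covered melanocyte lineage and pigment, the undifferentiated or neural crest state, glycolysis, oxidative phosphorylation, IGF and insulin signalling, H3K4 and H3K27 enzymes, MAPK targets, cell cycle and tumour suppressors, antigen presentation, Hox genes, other developmental regulators and housekeeping genes. Markers of fibroblasts, endothelial cells, immune cells and keratinocytes stood for other cell types. Lists, comparisons, the rule for named genes and most alternatives were fixed before the data were examined.

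The rule for named genes was as follows. Kmt2d came first, as the targeted gene. For each mark called against input in both lines and each direction, the peaks with no counterpart within 1 kb were ranked by the authors' p value, and the nearest protein-coding gene with an end within 100 kb was taken for each peak until there were 10 different genes. For the mutant H3K27me3 list, the first 10 genes with a region at a gene end were taken. From each gene list came the members whose promoter state differed between the lines and up to 4 members with the largest difference in covered bases. A few genes that the rule took are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

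No test between the lines was possible with 1 library per line and mark, so no difference has a replicate check and no p value is given across peaks or genes. The 95% intervals of shares are Wilson intervals and cover counting error only. Sequencing depth was not given, but the fold and p value of each H3K27ac peak allowed the number of fragments at its summit and its control background to be solved for, since MACS2 adds 1 to both in the fold and uses a Poisson tail for p. A whole number of fragments matched 100% of peaks in both lists within 0.002 on the −log10 scale. The median summit held 8 fragments in the WT list and 7 in the mutant list. Small counts of this kind limit how exactly any single narrow peak can be found again.

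Overlap, coverage, summit and list steps were tested on data with known answers. Part of the 26415 WT H3K27ac peaks were copied with a shift smaller than their width. Copied peaks were found in 100% of cases, and peaks that were not copied in 0%. This checks the overlap step, not whether narrow peaks can be found again in another library. Simulated summit counts were recovered in 100% of 5000 cases, and a whole count matched 1.7% of 2000 unrelated pairs of fold and p. For H3K27ac coverage, 5% of 40 unchanged gene lists fell outside the central 95% of random lists, and 100% of 40 raised lists lay above it. Alternatives changed the overlap rule, the promoter distance, the list lengths, the chromosomes used, the width of a broad domain and the window around genes. Each list outside the range of random lists was also placed without the member that differed most to that side, an alternative chosen after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.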

Results

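Peak lists of 4 histone marks were compared between a Kmt2d WT and a Kmt2d mutant mouse melanoma line, to ask how chromatin differs with Kmt2d genotype. The WT lists held 26415 H3K27ac, 17373 H3K4me1, 23154 H3K4me3 and 25394 H3K27me3 peaks on the assembled chromosomes. The mutant lists held 18751 H3K27ac, 3649 H3K4me1 and 17987 H3K4me3 peaks, and 1300 regions where H3K27me3 was higher than in the WT line. Each list came from 1 library, so the differences have no replicate check.

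Kmt2d itself (chromosome 15, 98831669 to 98874077) carried H3K4me3 at both gene ends in both lines. The peak at the upper end was 6.73 kb wide in the WT line and 6.45 kb wide in the mutant line, each with a score of 3100. That exact score recurs among the strongest peaks of both lists, so it does not show equal signal. At the lower end the peaks were 2.82 kb and 2.70 kb wide. An H3K27ac peak of 195 bp lay at the lower end in the mutant list alone and one of 380 bp (98871524 to 98871903) near the upper end in the WT list alone, so H3K27ac at a gene end no longer differed at a distance of 2.5 kb. Within 50 kb of the gene ends H3K27ac covered 0.966 kb in the WT line and 0.562 kb in the mutant line. Peaks at the gene ends do not read the mutation, so they do not check the labels.

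H3K4me1, the mark placed by KMT2D, had the fewest mutant relative to WT peaks of the 3 marks called against input in both lines. For every 100 WT peaks there were 21.0 mutant peaks (20.3 to 21.8), and the covered length was 9.44 Mb against 1.51 Mb, 6.27-fold more in the WT line. Around Nes, an intermediate filament gene of neural progenitors, H3K4me1 covered 11.3 kb in the WT line and 0 kb in the mutant line. Tead1, a Hippo pathway transcription factor, had 11.0 kb in the WT and 2.21 kb in the mutant line, and Col5a1, a fibrillar collagen, 13.2 kb and 0.319 kb. Igf2r, a receptor that clears IGF2, had 10.9 kb in the WT line and 1.62 kb in the mutant line. Distal H3K4me1 peaks numbered 19.6 in the mutant per 100 in the WT line, and promoter peaks 33.6 per 100.

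Of the WT H3K4me1 peaks, 6.63% (1151 of 17373) overlapped a mutant peak, against 0.149% of peaks placed at random. Within 1 kb the share was 11.6%, and among the strongest 5% of WT peaks it was 19.9% (17.4% to 22.7%). In the other direction, 47.2% (45.5% to 48.8%) of mutant peaks had a WT peak within 1 kb, so over 50% of the far shorter mutant list lay elsewhere. The strongest WT peaks without a counterpart lay near Arap3, Slc25a26, Atxn1, Txn2, Ncoa3, Psd3, Sun1, Foxo6, Abca4 and Asap2. That near Arap3, a GTPase-activating protein, had a −log10 p of 12.5 and its midpoint lay 16.6 kb from the gene end (chromosome 18, 38015981 to 38016242). The strongest mutant peaks without a counterpart lay near Pank4, Zfpl1, Tkfc, Ess2, Rsrp1, Ipmk, Cic, Ptprj and Ccp110, and 3 of these genes are on chromosomes 10 and 19.

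At gene ends, H3K4me1 was called at 104 genes in both lines, at 817 in the WT line alone and at 392 in the mutant line alone. With a promoter distance of 2.5 kb the counts for the WT and the mutant line alone were 1606 and 1122, and in lists of equal length the order turned, with 170 and 458. One gene list, oxidative phosphorylation and the TCA cycle, lay above random lists for H3K4me1 (percentile 99.5), with 6 members more covered in the mutant line and 9 less and a mean difference, mutant minus WT, of −0.0563 kb. Cs, citrate synthase, had 0.309 kb in the WT and 2.12 kb in the mutant line. Cs is on chromosome 10, and without chromosomes 10 and 19 the percentile was 90.9. Without Cs alone it was 94.8. The list stayed above the range in only 1 of 5 alternatives, the window of 20 kb. The other 15 lists lay inside the range of random lists, including the undifferentiated and neural crest list (percentile 7.82), to which Nes and Tead1 belong, and housekeeping genes (68.9).

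**Figure D1:**
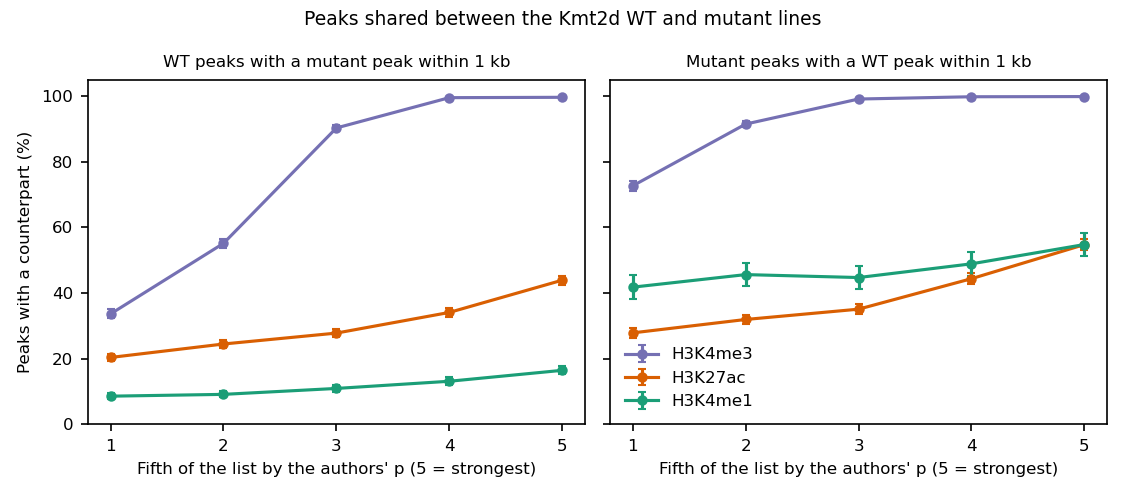
Share of peaks (percent) with a counterpart in the other line within 1 kb, against rank in 5 equal groups of the authors' p value within each list, with Wilson 95% intervals, for WT peaks (left) and mutant peaks (right). In the strongest 20% of WT peaks 99.7% of H3K4me3, 43.9% of H3K27ac and 16.4% of H3K4me1 peaks had a mutant counterpart, and in the weakest 20% 33.6%, 20.3% and 8.52%.

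H3K27ac, a mark of active enhancers and promoters, was also called less often in the mutant line, with 71.0 mutant peaks (69.7 to 72.3) per 100 WT peaks and 2.39 Mb covered against 3.62 Mb. Promoter peaks stood at 62.8 per 100 and distal peaks at 74.6 per 100. Around E2f1, a cell cycle transcription factor, coverage was 1.35 kb in the WT line and 0.277 kb in the mutant line. Nlrc5, the activator of MHC class I genes, had 1.07 kb in the WT line and 0 kb in the mutant line. Jun, an AP-1 subunit, differed the other way, with 0.576 kb more in the mutant line, and so did Cdh2, N-cadherin, with 0.088 kb in the WT and 0.617 kb in the mutant line.

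The H3K27ac peaks of the lines seldom coincided. A mutant peak overlapped 8.65% (8.31% to 8.99%) of WT peaks, against 0.207% of peaks placed at random, and lay within 1 kb of 30.1% (29.6% to 30.7%), against 1.59% at random. Within 1 kb, 43.0% of WT promoter peaks and 24.5% of WT distal peaks had a mutant counterpart. Of the strongest 5% of WT peaks, 50.9% (48.2% to 53.6%) had one. The strongest WT peaks without a counterpart lay near Prl2c3, Abl1, Adnp2, Crnkl1, Taf15, Ubb, Zfp945, Zcchc14 and Gli3. Prl2c3 belongs to a family of near-identical prolactin-related genes and its peak is uncertain. The peak at Abl1, a tyrosine kinase gene, had its midpoint 191 bp inside a gene end (chromosome 2, 31688358 to 31688511) with a 12.5-fold enrichment over input. The strongest mutant peaks without a counterpart lay near Phrf1, Kif2c, Ttc41, Erv3, Mfsd6, Fam204a, Srp9, Cdhr3, Efl1 and Htatip2, that at Phrf1 with 11.7-fold enrichment.

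Of the gene lists, 3 lay outside the range of random lists for H3K27ac. The undifferentiated, invasive or neural crest list stood above it (percentile 98.6), with 12 members more covered in the mutant line and 14 less, so its mean difference of −0.0686 kb was less negative than in random lists. Jun and Cdh2 are members, and so are Zeb2 and Axl, which had less. Axl, a receptor kinase of invasive melanoma cells, had 0.996 kb in the WT and 0.262 kb in the mutant line. Other developmental regulators stood below it (percentile 1.22), with 17 of 36 members less covered and 2 more, among them the T-box repressor genes Tbx2 (0.566 kb in the WT, 0 kb in the mutant line) and Tbx3 (0.640 kb and 0.103 kb). That list was inside the range without Tbx2 (3.49) and within a window of 20 kb. Genes for H3K4 and H3K27 enzymes stood just below it (percentile 2.48), with 24 of 27 members less covered, among them the deacetylase gene Hdac2 (0.725 kb in the WT, 0 kb in the mutant line) and the H3K27 demethylase gene Kdm6b (1.25 kb and 0.377 kb). That last position was lost in all 5 alternatives that were run, where the percentile was 3.28 to 7.93. The undifferentiated list stayed above the range in 4 of these 5, but was at 45.1 in the more significant 50% of each list. Without Jun it was at 96.2. The melanocyte list was at 42.5, although at single gene ends H3K27ac was called in the WT line alone at Mitf, Mlph and Met and in the mutant line alone at Pmel, Rab38 and Gpnmb. The call at Mitf was lost in lists of equal length and in the more significant 50%, and that at Pmel in the more significant 50%. Housekeeping genes were at 88.4, with 12 of 20 members less covered in the mutant line. The remaining lists lay inside the range, at percentiles from 4.27 for cell cycle and tumour suppressors to 97.2 for fibroblast markers. Fibroblast markers were above it within 100 kb (99.3).

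Distal H3K27ac peaks were split by H3K4me1, to ask whether both enhancer marks were missing from the same places. Of the 18369 distal WT peaks, 11.7% overlapped WT H3K4me1. A mutant H3K27ac peak overlapped 7.45% (6.42% to 8.64%) of those with H3K4me1 and 6.16% (5.80% to 6.55%) of those without it. Within 1 kb these shares were 29.7% (28.4% to 31.0%) and 22.6% (21.9% to 23.3%). Where H3K4me1 lay within 1 kb in both lines the share was 43.9% (40.5% to 47.4%), where it lay there in the WT line alone 26.9% (25.6% to 28.3%), and where it lay there in the mutant line alone 44.8% (40.5% to 49.3%). Where H3K4me1 lay there in neither line the share was 21.8% (21.1% to 22.5%). By 1 bp overlap the difference between peaks with and without H3K4me1 was 1.29 percentage points, and it was −1.20 in lists of equal length. In 5 equal groups by peak score, weakest first, 1 bp shares with H3K4me1 were 3.89%, 6.23%, 4.50%, 6.18% and 13.0%. Without it they were 3.02%, 4.31%, 4.61%, 6.74% and 12.7%. Within 1 kb the share with H3K4me1 was higher in each group, at 40.8% against 36.9% in the strongest.

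H3K4me3, the promoter mark, was largely shared. A mutant peak overlapped 93.4% (93.0% to 93.9%) of WT promoter peaks and 45.5% (44.6% to 46.5%) of WT distal peaks. There were 96.2 mutant promoter peaks and 54.4 mutant distal peaks per 100 in the WT line. Of the 5581 distal WT peaks without a mutant counterpart, 31.4% (30.2% to 32.6%) overlapped WT H3K4me1, against 12.4% (11.5% to 13.4%) of the distal peaks found in both lines, whereas 16.3% (15.3% to 17.3%) overlapped WT H3K27ac, against 30.5% (29.2% to 31.8%). Of the 991 distal peaks in the mutant list alone, 1.72% (1.07% to 2.73%) overlapped mutant H3K4me1, against 7.42% (6.69% to 8.21%) of the mutant distal peaks found in both lines, the opposite order to that in the WT line. Distal peaks of 1 line alone were weaker than those found in both, and the shares were not matched for strength. Their median scores were 88 against 354 in the WT and 85 against 244 in the mutant list. Domains at least 4 kb wide numbered 2207 in the WT line and 1737 in the mutant line, which was 9.53% and 9.66% of the peaks of each list.

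Sox10, the transcription factor that specifies the melanocyte lineage, was among the genes with the strongest H3K4me3 in the mutant line alone. A mutant peak of 6.66 kb with a score of 2876 covered chromosome 15, 79157964 to 79164621, at the upper end of the gene, where the WT line had no H3K4me3 peak and had an H3K27me3 peak of 5.98 kb. H3K27ac ran the other way, with 0.618 kb around Sox10 in the WT and 0.089 kb in the mutant line, and a WT peak of 88 bp inside that stretch. The others were Klhl1, S1pr3, Tenm4, Lgi4, Dmrtc1a, Glp2r, Irx2, Psd3 and Zfhx4. Lgi4, a glial ligand gene, had a peak of 4.73 kb. In the WT line alone the strongest peaks lay near Il17b, Dab2ip, Nkain2, Ifne, Ston1, Mtap, Pcolce, Cyth3, Spef1 and Cdsn. Pcolce, a collagen-processing protein gene, had a peak of 5.17 kb (chromosome 5, 137608818 to 137613991) that covered its upper gene end. The longest series of consecutive WT H3K4me3 peaks without a mutant counterpart held 21 peaks and ran from 88947341 to 89515597 on chromosome 4. It included the peaks assigned to Ifne and Mtap. These series were chosen after their values were seen. The next held 18 peaks over Zeb2, a neural crest transcription factor, which had 42.6 kb of H3K4me3 in the WT line and 23.0 kb in the mutant line.

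**Figure D2:**
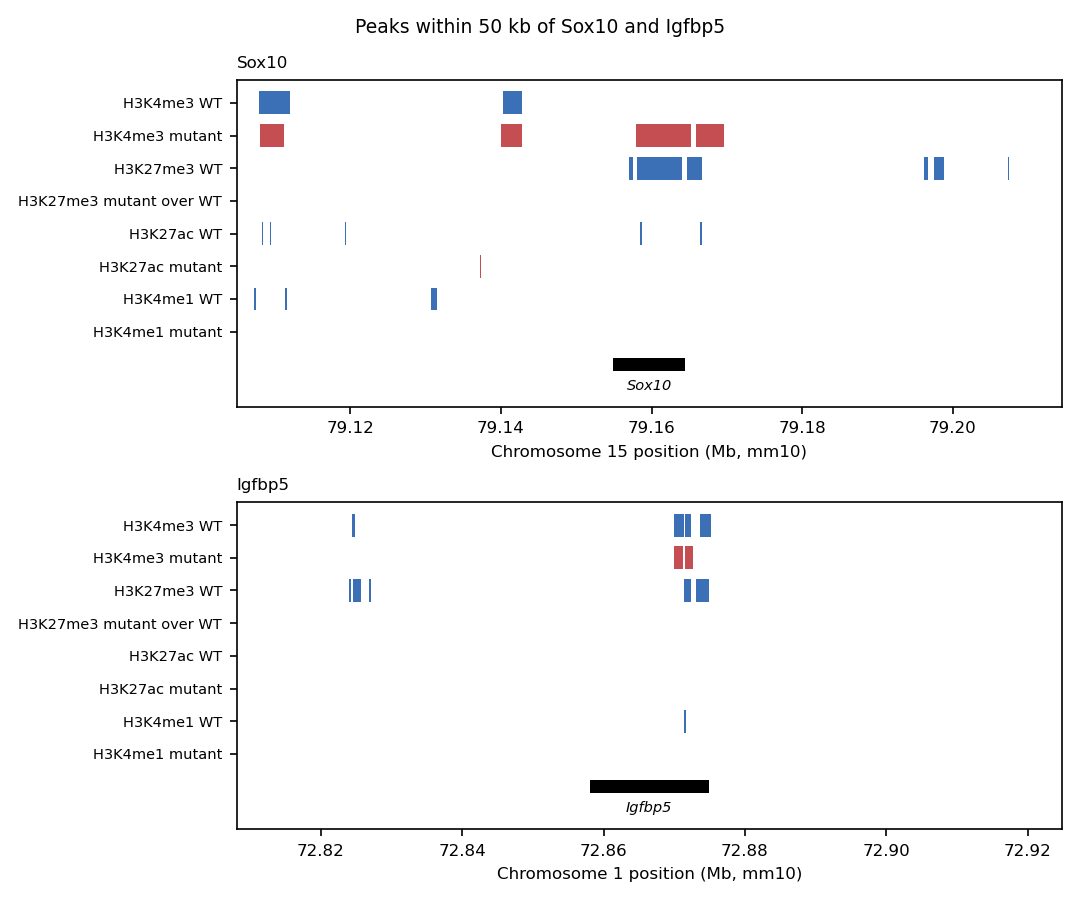
Peaks (boxes) of each mark and line within 50 kb of Sox10 and Igfbp5, along the chromosome in Mb on mm10, with the gene model in black. At Sox10 the mutant H3K4me3 peak of 6.66 kb lies over the WT H3K27me3 peak of 5.98 kb, and at Igfbp5 the WT peak of 1.58 kb at the upper gene end has no mutant counterpart while peaks further inside the gene are present in both lines.

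Of the gene lists, 6 lay outside the range of random lists for H3K4me3. Hox genes stood above it (percentile 100), with 34 of 39 members more covered in the mutant line, 3 less and a mean of 3.20 kb against 1.82 kb. Neighbouring Hox genes share the same peaks, so these members are not separate observations. Hoxa4, Hoxa7, Hoxb9, Hoxc5, Hoxd3 and Hoxd9 had H3K4me3 at a gene end in the mutant line alone and Hoxc9 in the WT line alone, and all 39 had WT H3K27me3. At 2.5 kb the difference at Hoxa7 and Hoxc9 was lost, and at Hoxc9 also in lists of equal length. The peaks were weak, with scores of 158 at Hoxa4 and 69.1 at Hoxd9. Other developmental regulators were also above the range (percentile 99.7), with 17 of 36 members more covered and 14 less. Pax2, a kidney and neural regulator, had 4.58 kb in the WT and 8.14 kb in the mutant line. Gata3 and Gata4 differed the other way, with 6.86 kb and 3.78 kb and with 6.52 kb and 3.99 kb. Foxa2, an endoderm regulator, had H3K4me3 at a gene end in the mutant line alone and Pax9 in the WT line alone, but Foxa2 not at 2.5 kb and Pax9 not in lists of equal length. Keratinocyte markers were at percentile 99.8, with Dsp, Perp and Grhl3, of desmosomes and the epidermal barrier, marked in the mutant line alone. Of the 12 keratinocyte genes, 4 were more covered in the mutant line, 2 less and 6 equal. The Hox, developmental and keratinocyte lists left the outer range in the more significant 50% of each list.

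Melanocyte lineage and pigment genes stood above random lists for H3K4me3 (percentile 99.8), a position that rested on Sox10. Without Sox10 the other 24 members were at percentile 90.3, inside the range, with a mean difference, mutant minus WT, of −0.213 kb. With Sox10 the mean coverage was 5.34 kb in the WT line and 5.55 kb in the mutant line, while random lists had a median difference, mutant minus WT, of −0.611 kb. Members differed in both directions, with 9 more covered, 12 less and 4 equal. Sox10 had 6.60 kb in the WT and 17.1 kb in the mutant line, and Gpnmb, a melanosome glycoprotein, 4.89 kb and 8.12 kb. Pax3, an upstream regulator of Mitf, had 16.1 kb and 11.0 kb. Sox10, Mlana and Slc45a2, the last pair pigment cell genes, had H3K4me3 at a gene end in the mutant line alone, and no member had it in the WT line alone.

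IGF and insulin signalling genes stood below random lists (percentile 0.66), with 20 of 26 members less covered in the mutant line. That count alone does not set the list apart, since 19 of 20 housekeeping genes, a list inside the range, were also less covered. Pik3r1, a PI3-kinase regulatory subunit, had 16.8 kb in the WT and 9.19 kb in the mutant line, Irs2, an insulin receptor substrate, 13.4 kb and 6.86 kb, and Igfbp6 12.3 kb and 5.96 kb. Igf2bp3, an RNA-binding protein gene, had more in the mutant line (8.94 kb and 14.2 kb). Igfbp5, an IGF-binding protein gene, had a WT peak of 1.58 kb (score 250) at its upper end and none there in the mutant line, and Igfbp2, its neighbour, a WT peak of 0.490 kb (score 57.0). A mutant peak (72871571 to 72872584) lay within 2.5 kb of the Igfbp5 end, so its state there did not differ at that distance. At Igf1 a mutant peak of 2.72 kb (score 1793) lay at a gene end and no WT peak did, but this state did not differ at 2.5 kb. That peak is not among the strongest mutant peaks without a WT peak within 1 kb. Fibroblast markers were also below random lists (percentile 0.49), with Col1a2, a collagen I chain, at 7.88 kb and 0 kb and Thy1 at 9.89 kb and 3.95 kb. Each of these lists left the outer range in 3 of 5 alternatives, and the fibroblast list was at 7.15 without Col1a2.

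The other 10 lists lay inside the range for H3K4me3. The undifferentiated or neural crest list was close to its lower edge (percentile 2.67), with 18 of 27 members less covered, among them Tead1 (16.3 kb in the WT, 9.70 kb in the mutant line) and Nes (20.7 kb and 15.0 kb). Oxidative phosphorylation was at 96.7, antigen presentation at 94.0, H3K4 and H3K27 enzymes at 89.9, cell cycle and tumour suppressors at 66.7, immune markers at 58.0, glycolysis at 49.1, endothelial markers at 43.6, housekeeping genes at 35.8 and MAPK targets at 15.4. Cdkn1a, a cyclin-dependent kinase inhibitor of the tumour suppressor list, had H3K4me3 at a gene end in the WT line alone (2.38 kb, score 295), although not at 2.5 kb. Of the 15 list members with H3K4me3 in the mutant line alone, 12 kept that state at 2.5 kb, 15 in lists of equal length and 2 in the more significant 50%. Of the 6 in the WT line alone, 3, 2 and 0 kept it, with Igfbp2 and Thy1 also lost in lists of equal length.

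**Figure D3:**
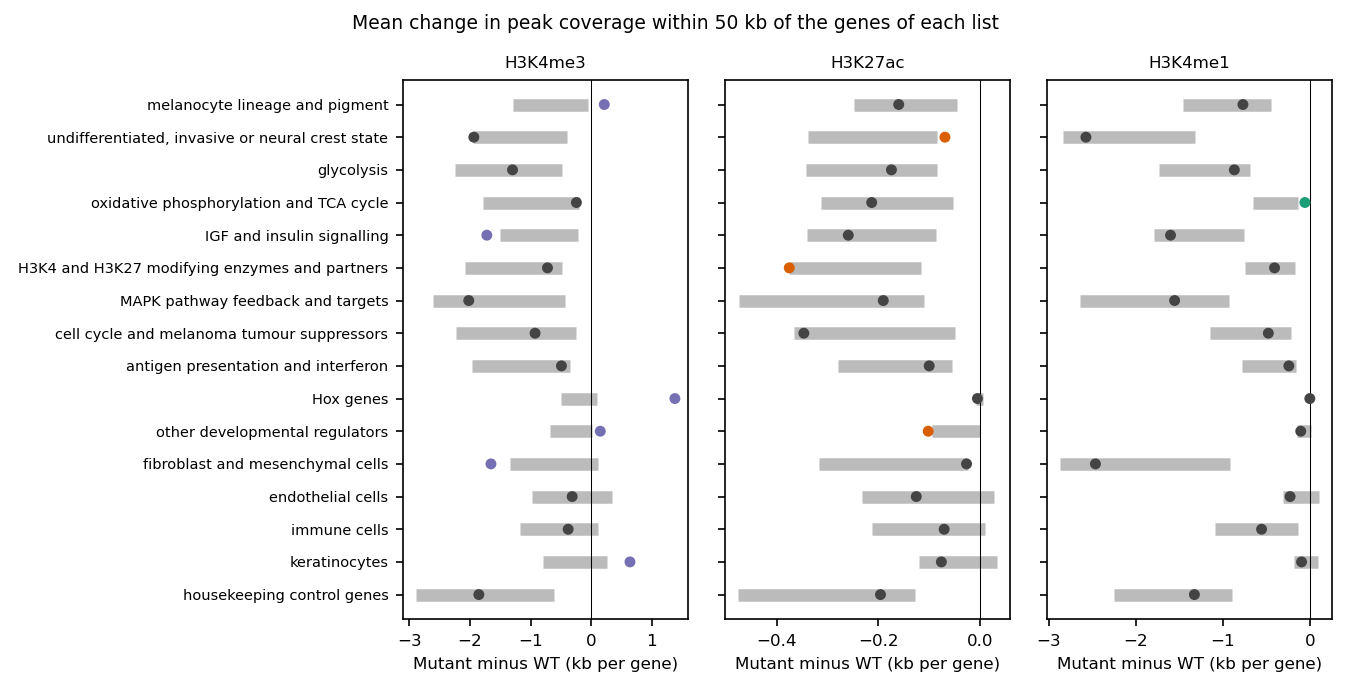
Mean difference in covered bases per gene, mutant minus WT in kb, within 50 kb of the genes of each list (points), beside the central 95% of 10000 random lists (grey bars), for H3K4me3, H3K27ac and H3K4me1. Coloured points lie outside the grey bars, for H3K4me3 the melanocyte, Hox, developmental and keratinocyte lists above and the IGF and fibroblast lists below.

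H3K27me3, the Polycomb mark, formed its widest WT peaks over developmental genes. The widest, 25.4 kb on chromosome 6 (52193611 to 52218974), covered ends of Hoxa3, Hoxa5, Hoxa6 and Hoxa7, and the next lay over Tlx1 (18035 bp) and over Hoxb3 and Hoxb4 (17017 bp). WT H3K27me3 lay at the ends of 2176 genes, of which 1069 also had WT H3K4me3, and 1000 of these (93.5%) had H3K4me3 in the mutant line too. WT H3K27me3 marked 35.6% (30.9% to 40.6%) of the 368 genes with H3K4me3 in the mutant line alone, 23.1% (18.7% to 28.2%) of the 299 with it in the WT line alone and 8.31% (7.83% to 8.81%) of the 12040 with it in both. In lists of equal length the counts of genes with H3K4me3 in one line alone were 565 for the mutant and 185 for the WT line, and in the more significant 50% of each list the order turned, with 63 and 1586. That last cut fell at each list's own median score, 639 in the WT and 1217 in the mutant list. Peaks with scores between these in both lines stayed in the WT list alone, so this cut by itself favours the WT line alone.

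The 1300 regions with more H3K27me3 in the mutant than in the WT line were short, with a median width of 162 bp and 0.269 Mb in all. None overlapped a WT H3K27me3 peak (0%, upper limit 0.295%), against 0.925% of regions placed at random, but a list called against the WT H3K27me3 library leaves out places with much WT H3K27me3 by construction. At gene ends lay 6.08% (4.90% to 7.51%) of the regions, against 5.25% of those placed at random. The strongest of these lay at Cibar2, Basp1, Slc24a4, T, Fli1, Npas4, Cbln2, Pcdh12, Krt27 and Rab20. The region at T, the mesoderm regulator brachyury, was 151 bp wide with 5.04-fold enrichment over the WT library. T also had a WT H3K27me3 peak at a gene end, although not overlapping this region. A mutant H3K27me3 list called against input is not used here, so gains or losses of whole Polycomb domains were not measured.

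The ratio of mutant to WT peaks was uneven over chromosomes. On chromosomes 10 and 19 there were 92.8 and 116 mutant H3K27ac peaks per 100 WT peaks, against 61.3 to 77.8 on the other 17 autosomes. For H3K4me1 the values were 36.8 and 44.6, against 16.1 to 23.2. For H3K4me3 they were 79.4 and 84.4, against 71.4 to 81.3, so chromosome 10 lay inside the range of the others. Regions with more H3K27me3 in the mutant line numbered 1.05 and 1.53 per Mb, against 0.233 to 0.716. These chromosomes carry Igf1, Perp, Cs and Pmel (chromosome 10) and Mlana (chromosome 19). Chromosome X also lay above the other 17 autosomes for H3K4me3 (90.7), for H3K4me1 (42.1, from only 19 WT peaks) and for H3K27me3 regions (0.721 per Mb). For H3K27ac it lay inside their range (73.8).

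**Figure D4:**
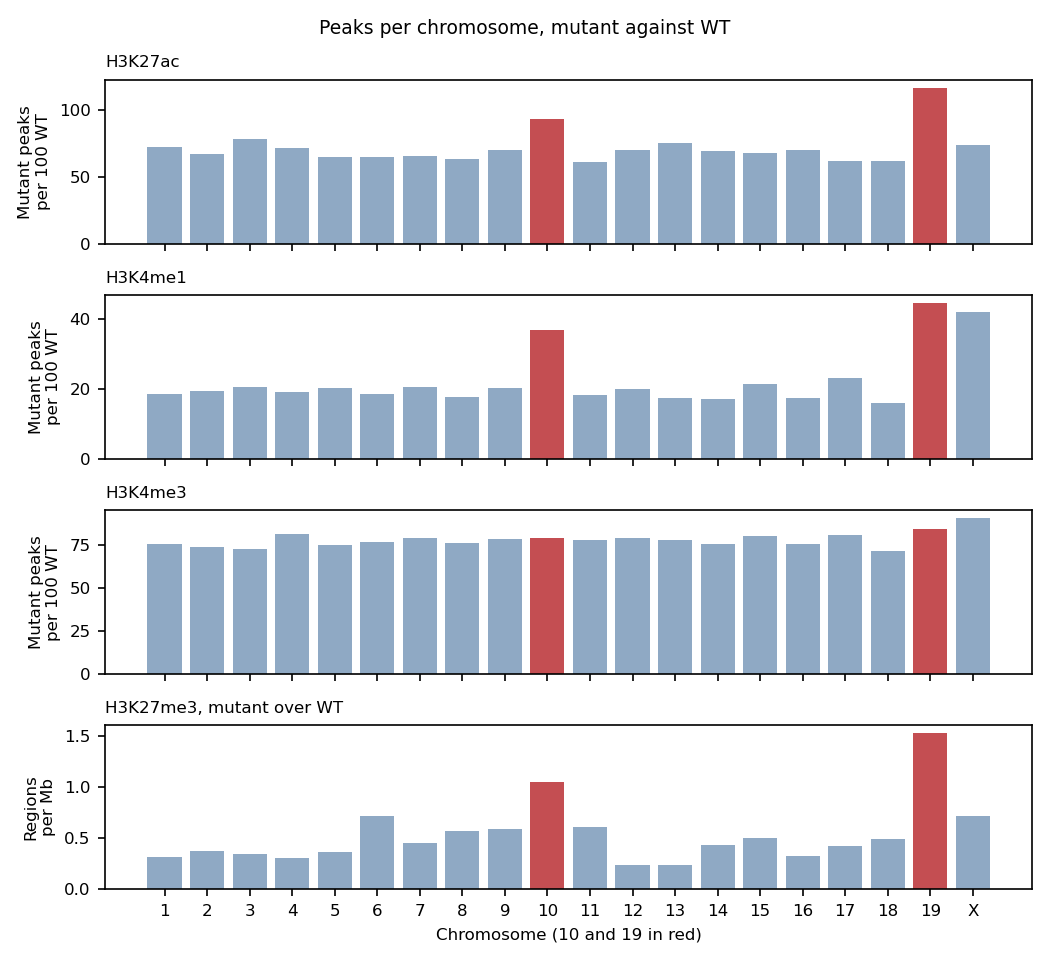
Mutant peaks per 100 WT peaks on each chromosome for H3K27ac, H3K4me1 and H3K4me3, and regions per Mb with more H3K27me3 in the mutant than in the WT line, with chromosomes 10 and 19 in red. For H3K27ac chromosomes 10 and 19 stand at 92.8 and 116, above the 61.3 to 77.8 of the other autosomes.

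Around Cdkn2a, the gene of the tumour suppressors p16 and p19, each line had a stretch without peaks, and the stretches were offset. In the mutant line no H3K27ac, H3K4me1 or H3K4me3 peak lay between 88950460 and 89350477 on chromosome 4 (400 kb), where the WT line had 24 H3K27ac, 16 H3K4me1 and 18 H3K4me3 peaks. In the WT line no peak of any of the 4 marks lay between 89164858 and 89514737 (350 kb), where the mutant line had 17 H3K27ac and 5 H3K4me1 peaks. The stretches overlapped by 186 kb, which held Cdkn2a, Cdkn2b and part of Mtap. Mtap, a methionine salvage enzyme gene, had 14.1 kb of H3K4me3 within 50 kb of its ends in the WT line and 0 kb in the mutant line. The region was examined because the named peaks near Ifne and Mtap fell in it, and Cdkn2b was chosen after its values were seen.

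**Figure D5:**
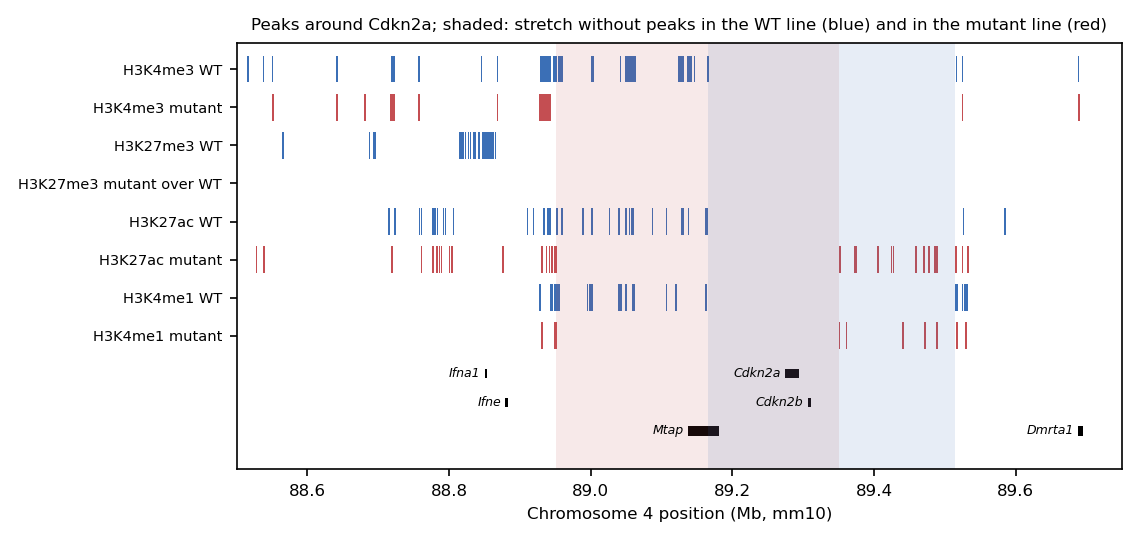
Peaks (vertical bars) of each mark and line around Cdkn2a, by position in Mb on chromosome 4 of mm10, with gene models in black. The red shading marks the 400 kb without mutant H3K27ac, H3K4me1 or H3K4me3 peaks and the blue shading the 350 kb without WT peaks, which overlap over Cdkn2a and Cdkn2b.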

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

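Tests of H3K27ac sequencing depth, of the H3K4me1 library, of lost marks at Cdkn2a, of other dense windows, and of background without the lowest peaks and at shared peaks were chosen only after the result was seen.

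On contigs outside the assembled chromosomes, which no comparison used, the WT H3K4me3 list had 10 peaks and the mutant list 7, against a limit of 3 for a count of 0.

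Around Cdkn2a the mutant lists were empty over 400 kb where the WT line had 58 peaks, and the WT lists over an offset 350 kb where the mutant line had 22, with H3K27ac at 11.1 and 10.3 peaks per 100 kb over the part with peaks, against 0.981 and 0.697 genome-wide. Of 122 and 490 other windows with as many peaks of the other line, 0 and 0 were empty, so the region is unusual. An empty stretch would follow from loss of DNA or from loss of marks in that line. Extra copies in the other line would add peaks there. No value here shows that they would empty the mutant line, where H3K4me3 was missing around Mtap too. The 186 kb without peaks in both lines, which held Cdkn2a and Cdkn2b, was not tested. The background under the H3K27ac peaks there was 2.20 times the genome median in the WT line (1.46 to 2.51) and 2.39 times in the mutant line (1.35 to 2.83), as predicted for extra copies in the line with peaks, yet 4 of 42 and 3 of 67 other windows with as many H3K27ac peaks were as high, so extra copies stay open. Loss of the active marks from DNA that is still present stays open too, since 0 regions with more H3K27me3 in the mutant line lay in its empty stretch, where only 0.193 would by their genome density. These explanations cannot be told apart without input reads, which were not analysed here.

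Chromosomes 10 and 19 held more mutant relative to WT H3K27ac peaks than any other autosome. A few active loci were argued against, since 85% of their 10 Mb bins (17 of 20) lay above the genome ratio, compared with 41.8% elsewhere. That count hides a regional pattern on chromosome 10. Its bins from 80 Mb on held 106 to 193 mutant per 100 WT peaks, and its earlier bins 51.4 to 84.0. By a rule that either chromosome could meet, a test of background argued against extra DNA copies of these whole chromosomes in the mutant line. The background inferred under peaks, mutant over WT, was 0.791 (standard error 0.0150) on chromosome 10 and 0.779 (0.0205) on chromosome 19. The other autosomes had a median of 0.851 (0.823 to 0.881), and copies would raise this ratio. It was not raised either without peaks at the lowest background (0.819 and 0.831, others at least 0.838) or at peaks called in both lines (0.850 and 0.790, others 0.790 to 0.913), although there chromosome 10 lay within 1 standard error (0.0229) of the others' median. Without the lowest peaks the standard error on chromosome 19 was 0.0219 and the others' median 0.869. Neither chromosome was clearly below that median in both checks, so the test does not settle either one alone. Summit fragments at the shared peaks, mutant over WT, were 0.954 and 0.967, above the others (0.847 to 0.910), which copies would also give. Copies could also give the regions with more H3K27me3 in the mutant line (1.05 and 1.53 per Mb, others at most 0.716). By its name that list was called against the WT H3K27me3 library. The background test averaged called peaks over each whole chromosome, so it cannot exclude copies of part of chromosome 10. What sets these chromosomes apart stays open.

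The mutant line had fewer H3K27ac and H3K4me1 peaks. Lower depth was argued against for H3K27ac, where the genome-wide background per base was 1.01 times that of the WT library, although the median background under peaks, which follows the input and the peaks called, was 0.481 in the mutant and 0.607 in the WT list. Weaker H3K27ac enrichment across the library cannot be told apart from a loss of the mark, since at 2284 shared peaks the median ratio of summit fragments was 0.889, with fewer fragments in the mutant line at 1300 and more at 668, as either would give. For H3K4me1, 47.2% of mutant peaks had a WT peak within 1 kb. That lay between the limits set for a weaker library alone (90% or more) and for unrelated lists (under 10%). Both limits were assumed and not calibrated on data, so depth or enrichment stays open. The Kmt2d mutation is a biological explanation that was not tested, because each genotype is 1 line and any other difference between the lines goes with it.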

How the results depend on the processing

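No paired analysis was possible because each line and mark has 1 library, and leaving out a library was impossible for the same reason. Alternatives without chromosomes 10 and 19, with joined peaks and without the list member that differed most were chosen after seeing the data. The alternative with only the most upstream transcription start was not run, since the gene table has no strand. Of 81 alternative values of the main results, 42 stayed within their limits (the interval, or 1.5 times for counts), 38 moved and 1 reversed. Of 280 others 233 stayed, 47 moved and 0 reversed. Counts could only be labelled as stayed or moved, so the turned orders of H3K4me1 and H3K4me3 gene counts are not among those reversed. Where values moved, the cause was not tested. Small summit counts and the unknown depth of the other marks limit all shares.

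Without chromosomes 10 and 19 there were 68.0 mutant H3K27ac and 19.3 mutant H3K4me1 peaks per 100 WT peaks, and with peaks within 1 kb joined 75.7 and 24.1. The share of WT H3K27ac peaks with a mutant peak was 6.04% for 50% of the shorter peak, 30.1% within 1 kb, 8.13% in the more significant 50% of each list, 10.3% in lists of equal length and 11.5% with joined peaks. For H3K4me1 these shares were 5.26%, 11.6%, 4.75%, 9.78% and 7.76%, and 6.20% without chromosomes 10 and 19. For H3K4me3 the first 4 were 71.2%, 75.7%, 77.8% and 86.2%. Domains of at least 3 kb numbered 86.8 per 100. Within 1 kb, 0.692% of regions with more H3K27me3 in the mutant line had WT H3K27me3.

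The difference in shared distal H3K27ac peaks with and without H3K4me1 was 7.14 percentage points within 1 kb and 0.0523 in the more significant 50%, and reversed to −1.20 in lists of equal length.

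Genes with H3K4me1 in the WT line alone numbered 1606 at 2.5 kb, 170 in lists of equal length and 447 in the more significant 50%, and those in the mutant line alone 1122 at 2.5 kb and 232 in the more significant 50%. For H3K4me3 in lists of equal length and in the more significant 50% there were 185 and 1586 genes in the WT line alone, and 565 and 63 in the mutant line alone. The number of gene lists outside the range of random lists was 1 for H3K27ac within 20 kb and 5 in the more significant 50%. For H3K4me1 it was 2 within 100 kb, 2 in the more significant 50% and 0 without chromosomes 10 and 19, and for H3K4me3 1 in the more significant 50%.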

Other observations

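The test of cell states was chosen only after the result was seen. MAPK target genes lay inside the range of random lists for each mark within 50 kb, but above it for H3K27ac within 100 kb (percentile 98.1) and in the more significant 50% (98.7). They had single members with large differences. Epha2, an ephrin receptor gene, had 19.9 kb of H3K4me3 in the WT and 9.24 kb in the mutant line, and 8.30 kb and 0.736 kb of H3K4me1. Dusp5, an ERK phosphatase gene, had 5.73 kb and 0 kb of H3K4me1, and Ccnd1, cyclin D1, 6.98 kb and 1.40 kb. Among the 18 members all had H3K4me3 at a gene end in both lines.

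H3K4me3 and H3K4me1 at gene ends overlapped in the WT line. Of the 299 genes with H3K4me3 in the WT line alone, 48 were among the 817 with H3K4me1 in the WT line alone, where 11.2 would be shared if the sets were independent. In the mutant line alone 0 of 368 and 392 were shared, where 6.59 would be. Gene sets share neighbours, so these counts carry no test.

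A hypothesis is that the lines may sit in different melanoma cell states, the mutant line nearer to a melanocytic one. It required the melanocyte list above and the undifferentiated list below random lists for H3K4me3. The melanocyte list was at percentile 99.8, and the undifferentiated list at 2.67, just inside the 2.5 limit, so the test left the hypothesis open. The undifferentiated list was at 0.11 within 100 kb, 1.52 without chromosomes 10 and 19, 19.2 within 20 kb and 42.9 in the more significant 50%. For H3K27ac it stood above random lists (98.6), which goes the other way. That position held in 4 of 5 alternatives, but not in the more significant 50% (45.1), and was also lost without Jun (96.2). For H3K27ac the melanocyte list was at 42.5, and at 2.29, below random lists, in the more significant 50%, with less around Sox10, Pax3, Mc1r and Met in the mutant line. The Hox (100) and keratinocyte (99.8) lists also stood above random lists for H3K4me3, so that position is not specific to melanocyte genes. The melanocyte position also rests on Sox10, which had 10.5 kb more in the mutant line. Without Sox10 the list was at 90.3, so a difference at that gene alone would give the same result. No expression data were analysed here.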
